A study of Mus musculus with 8 samples.

How the data were processed

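Total RNA from mouse testis was measured on 8 Affymetrix MG_U74Av2 arrays, 2 for each of 4 genotypes: wild type, Terc knockout, Ku86 knockout (Ku86 is the protein of the Xrcc5 gene) and double knockout. Per the labels, mice without Terc, the RNA template of telomerase, were of the third generation without it. The scanner's text records call the samples germ cells, whereas the labels call the source testis, and both descriptions are kept here. Those records give 15 micrograms of cRNA per array, a pool of 3 mice for double knockout replicate 1, and a repeated hybridisation for wild type replicate 1. They also give 3 scan days. Day 1 held double knockout replicate 1 and Ku86 knockout replicate 1, day 3 held wild type replicate 1 alone, and day 2 held the other 5 arrays, with every genotype among them. The chip lot changed with the scan day, so lot and day cannot be told apart.

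The deposited values were probe set intensities on a linear scale, which the authors had scaled array by array. The mean without the top and bottom 2% of probe sets lay between 200.13 and 200.16 on every array. The authors' software is not given in the sources used here. The values were kept as deposited, because these trimmed means lay within 5% of their mean. Values below the pooled 20th percentile, a signal of 11.8, were set to it, and log2 was taken. Of 12488 probe sets, 66 controls were left out, and 5140 were left out because their mean over all 8 arrays was under the pooled 40th percentile, a signal of 38.1. The remaining 7282 probe sets were tested. Of all probe sets, 10855 had exactly 1 gene symbol, 396 had several and 1237 were listed with none. No genome sequence or probe positions were used, so genes are given without coordinates, and the gene table of assembly GRCm38.p6 served only for names and for gene order.

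Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on mean signal) to all 8 arrays, with 1 mean per genotype. The 8 contrasts were each knockout and the double knockout against wild type, the double knockout against each single knockout, the interaction, and the effect of each loss averaged over the other genotype. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all probe sets of a contrast. All tests were two-sided. The rule for scaling, the contrasts, the rule for named genes and the gene lists were fixed before the data were examined. Of the named genes, Xrcc5 and Terc came first. Next came probe sets with 1 symbol and groups that did not overlap, taking up to 12 called in each direction against wild type and up to 6 elsewhere. Where fewer passed, the list was filled to 6 or 3 with the largest changes at unadjusted p under 0.01, which are values and not calls. The 23 gene lists were p53 targets and DNA damage response, non-homologous end joining, homologous recombination and break signalling, telomere maintenance, spermatogonia, spermatocytes and meiosis, round spermatids, elongating spermatids, Sertoli cells, Leydig cells, peritubular, vascular and matrix, macrophage and immune, erythroid, epididymis, apoptosis, proliferation, cyclin-dependent kinase inhibitors and senescence, antioxidant, heat shock and unfolded protein, immediate early, insulin-like growth factor axis, interferon response, and oxidative phosphorylation. Each list was tested in each contrast with camera in limma on 5530 genes, the brightest probe set of each, with a preset inter-gene correlation of 0.01. The 184 list tests were adjusted together, and camera with an estimated correlation was run beside them. That form also draws its p from the few residual degrees of freedom of the fit. Its p can therefore rise even where genes of a list do not correlate. Single values of 4 arrays against 4 had an exact permutation test over 70 groupings.

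Alternatives covered quantile normalization, median centring, the floor, the filter, the variance trend, the arrays in the fit, the experiment number or scan day as a block, the threshold, and each array left out in turn. Lists were also tested on the mean of a gene's probe sets. The fit to scan day 2 alone was added after the data had been seen, as were the list tests with scan day as a block and with median centring. The pipeline was tested on simulated data with the spread of each probe set on these arrays, drawn independently for each probe set. In the double knockout against wild type it called 40% of probe sets moved by 1 on the log2 scale, 84% of those moved by 2 and 98% of those moved by 3. It made 10 false calls in that comparison and 0 in a comparison with no change. The shares recovered came from many probe sets moved at once, which loosens the adjusted threshold. With few changed probe sets the threshold is stricter, so low counts of calls do not exclude changes of these sizes. A list of 17 genes moved by 0.5 passed camera at an unadjusted p under 0.05 in 100% of 50 simulations, and an unmoved list in 2%. Simulated genes were uncorrelated, whereas the estimated correlation of the Sertoli list was 0.188. The simulations therefore do not check the list test where genes of a list correlate. Figures were drawn with matplotlib 3.10.9. The labels do not say that replicates came from separate animals, so a p measures only the spread between these samples, and the number of arrays limits the precision.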

Results

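The series recorded testis gene expression on 8 arrays, with 2 arrays for each combination of Ku86 and Terc genotype. Ku86, encoded by Xrcc5, is a DNA end-binding protein of non-homologous end joining that also binds telomeres, and Terc is the RNA of telomerase. Median signal per array ran from 49.6 on wild type replicate 1 and 59.3 on wild type replicate 2 to 73 on Terc knockout replicate 2, in arbitrary intensity units. Between 15.6% and 26.0% of probe sets per array lay at or under the floor. Correlations between arrays, across probe sets, ran from 0.91 to 0.959. The first principal component held 27.8% of the variance and was lowest on wild type replicate 1 (-35.1) and highest on Terc knockout replicate 2 (27.0).

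Xrcc5, the gene targeted in the Ku86 knockout, had its higher signal on the arrays labelled Ku86 knockout. Its mean was 390 ± 89.3 (SD, n = 4) on the arrays labelled Ku86 knockout and 51 ± 29.6 (SD, n = 4) on those labelled with Ku86. The lowest of the former, 259, was 3.43 times the highest of the latter, 75.6 (exact permutation p = 0.0286 over 70 groupings, two-sided, the smallest they can give). This direction is opposite to that of a lost transcript. The position of the probes in the transcript is not known here, and a probe outside the deleted part checks nothing, so genotypes are named below by their labels. A second Xrcc5 probe set stayed at or under 3.4 on every array and was not tested. Terc had no probe set. Xrcc6, which encodes the partner of Ku86, read 86 ± 19.8 on the arrays labelled Ku86 knockout and 102 ± 25.8 on the others (SD, n = 4 each). Tert, the protein subunit of telomerase, read 124 ± 15.6 and 119 ± 36.8, and both genes overlapped between the labels.

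**Figure D1:**
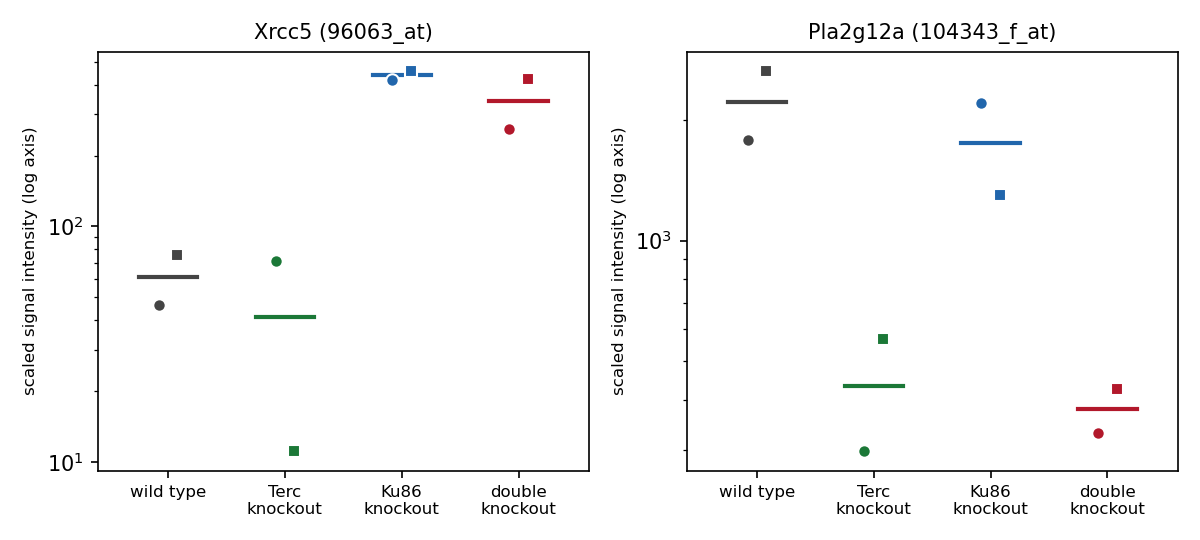
Signal of Xrcc5 and of Pla2g12a on each of the 8 arrays (y axis, intensity in arbitrary units, log scale) by labelled genotype (x axis), with a circle for replicate 1, a square for replicate 2 and a bar at the group mean. Xrcc5 read 259 or more on the 4 arrays labelled Ku86 knockout and 75.6 or less on the others, and Pla2g12a had means of 432 and 378 on the arrays labelled Terc knockout and double knockout against 2220 and 1760 on those labelled wild type and Ku86 knockout.

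The arrays labelled Terc knockout were compared with wild type to ask what losing telomerase RNA alone does in the testis. Hus1, a component of the DNA damage checkpoint clamp, rose 17.9-fold, from 14 ± 0.424 to 253 ± 54.5 (SD, n = 2 each). Pla2g12a, a secreted phospholipase, fell from 2220 ± 622 to 432 ± 191 (SD, n = 2 each). Sertoli cell genes and peritubular, vascular and matrix genes rose as lists, and cyclin-dependent kinase inhibitors fell as a list. The insulin-like growth factor axis also rose. With an estimated correlation none of these list calls held (adjusted p = 0.660 for Sertoli genes and 0.605 for the other 3 lists). Limma called 2 of 7282 probe sets, with 514 (7.06%) at an unadjusted p under 0.05. The log2 difference of Hus1 was 4.16 ± 0.552 (SE, adjusted p = 0.0488), and within scan day 2 it was 4.19. It was 4.16 with the floor at the 5th percentile and 2.71 with the floor at the 40th percentile. With no floor but an offset of 11.8 added to every value it was 3.34. Wild type stood at 14, over the floor of 11.8. Pla2g12a differed by -2.41 ± 0.338 (SE, adjusted p = 0.0488) and by -2.70 within scan day 2, and its other probe set differed by -1.41. The calls of both genes ended after quantile normalization, with the floor at the 5th percentile and with no filter. They also ended with no variance trend and with the experiment number as a block. Scan day as a block brought their adjusted p to 0.264 and 0.237, and both calls ended without either wild type array and without Terc knockout replicate 1 (counts of 0, 0 and 1). Without Terc knockout replicate 2 Hus1 also lost its call, in a count of 4. Uncalled genes with the largest differences were Tmem129 (2.83), Ube2f (2.47), Ift46 (2.39), Mpp3 (2.35) and Gfi1b (2.22) on the higher side. On the lower side they were Scx (-2.62), Sin3b (-1.87), Epor (-1.78), Golph3l (-1.69) and H2-Q4 (-1.65), and the lowest adjusted p among these 10 was 0.11. Other probe sets differed by -0.265 for Tmem129, -0.368 for Ift46 and -0.226 for Sin3b. Mpp3 read 11.5 and 12.7 in wild type, close to the floor of 11.8. Xrcc5 differed by -1.03 ± 0.634 (SE, adjusted p = 0.681).

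The median of all probe sets lay 0.107 above wild type in the Terc knockout, 0.0954 above it in the Ku86 knockout and 0.0754 above it in the double knockout, on the log2 scale. Quantile normalization brought these to 0.00336, 0.0115 and -0.0212, so the medians of passing lists against wild type are also given relative to the median of all genes. In the Terc knockout the 17 Sertoli cell genes had a median of 0.556, which was 0.464 above all genes, with 15 of 17 above 0 (adjusted p = 0.00426, and adjusted p = 0.660 with an estimated correlation). The median was 0.433 with scan day as a block, which in this comparison must equal the value within scan day 2. Aard, Fshr, Dhh and Gata1 had the largest moderated t, with differences of 0.56, 0.62, 0.53 and 0.75, although that of Dhh lay under the list's median, and 0 members passed over all or adjusted over the list alone. The 16 peritubular, vascular and matrix genes had a median of 0.517, which was 0.425 above all genes (adjusted p = 0.00335, and adjusted p = 0.605 with an estimated correlation). It was 0.322 with scan day as a block, within scan day 2 and without wild type replicate 1. In this comparison all these settings set the Terc knockout arrays against wild type replicate 2, so they give the same value by design. Timp2 and Myh11 (smooth muscle myosin) passed adjusted over the list alone, Timp2 with a difference of 1.70 and Myh11 at least 3.78-fold higher with wild type at the floor, and 0 members passed over all. Without wild type replicate 2 the adjusted p was 0.0848 for both lists, and without Terc knockout replicate 1 it was 0.0701 for the Sertoli cell list.

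The 8 kinase inhibitor and senescence genes had a median of -0.285, which was -0.376 relative to all genes (adjusted p = 0.0462, and adjusted p = 0.605 with an estimated correlation). Cdkn1c, a cyclin-dependent kinase inhibitor, passed adjusted over the list alone at -1.02 ± 0.242 (SE), from 1850 ± 505 to 909 ± 251 (SD, n = 2 each). The list's median was -0.436 after quantile normalization and -0.191 within scan day 2. After median centring it was -0.416 and the list's call ended (adjusted p = 0.0735). The call ended with scan day as a block (-0.191, adjusted p = 0.332), after quantile normalization (adjusted p = 0.0673) and without Ku86 knockout replicate 1 (adjusted p = 0.0504) or either wild type array (0.272 and 0.0516). Without Terc knockout replicate 2 the median was -0.0476 (adjusted p = 0.27), and without replicate 1 it was -0.481 (adjusted p = 0.0289). The 12 insulin-like growth factor genes had a median of 0.515, 0.424 above all genes (adjusted p = 0.0139, and adjusted p = 0.605 with an estimated correlation), and 0.491 with scan day as a block (adjusted p = 0.00131). Without Terc knockout replicate 1 its adjusted p was 0.0809, and without wild type replicate 2 it was 0.307. Foxo3 (1.07) and Igf2 (0.78) had the largest moderated t, and 0 members passed over all or adjusted over the list alone. Tk1, thymidine kinase of the proliferation list, passed adjusted over its list alone at 2.08 ± 0.388 (SE), and Cox6c of oxidative phosphorylation at -0.68 ± 0.161 (SE).

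The arrays labelled Ku86 knockout were compared with wild type, a comparison that by its labels asks about losing Ku86 alone, although Xrcc5 was higher on these arrays (439 ± 27.5) than in wild type (61 ± 20.7; SD, n = 2 each). Tmem129, a ubiquitin ligase of the endoplasmic reticulum, rose 11.8-fold, from 46.2 ± 14.2 to 545 ± 167 (SD, n = 2 each). Ift46, an intraflagellar transport protein, rose 6.85-fold, from 42.5 ± 1.41 to 294 ± 62.4. Klk1b8, a kallikrein protease, fell from 255 ± 44.6 to 65.5 ± 9.48. Sertoli cell and peritubular lists rose, and oxidative phosphorylation fell as a list. With an estimated correlation these list calls did not hold (adjusted p = 0.780, 0.605 and 0.605). Limma called Tmem129, Ift46 and Klk1b8, 3 probe sets of 7282, each at an adjusted p of 0.0447, with 430 (5.9%) at an unadjusted p under 0.05. Their log2 differences were 3.56 ± 0.503, 2.78 ± 0.382 and -1.95 ± 0.284 (SE), and within scan day 2 they were 2.92, 2.52 and -2.28. Another probe set of Tmem129 differed by -0.29, another of Ift46 by -0.13 and another of Klk1b8 by 0.033. All 3 calls ended after quantile normalization or median centring, with no filter, with no variance trend and with the experiment number as a block. After blocking on scan day the adjusted p was 0.665, 0.528 and 0.441, and the count was 0 without either wild type array and without either Ku86 knockout array. Klk1b8 lost its call without any 1 of the 8 arrays. Xrcc5 was higher on the arrays labelled Ku86 knockout by 2.89 ± 0.634 (SE, adjusted p = 0.369), against the direction of its label. Other uncalled genes were Myh11 (at least 5.38-fold higher, with wild type at the floor), Mpp3 (2.36, with wild type close to the floor) and Ube2f (2.20) on the higher side. Scx (-3.37), Gpaa1 (-2.20), Rnf20 (-2.18), Fcgbp (-1.96) and Mapkapk2 (-1.90) stood on the lower side. Their other probe sets, where tested, differed by -0.223 for Gpaa1, 0.535 for Rnf20, -0.511 for Fcgbp and -0.00142 for Mapkapk2.

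Sertoli cell genes had a median of 0.386 in the Ku86 knockout, 0.302 above all genes, with 13 of 17 above 0 (adjusted p = 0.0342, and adjusted p = 0.780 with an estimated correlation). The median was 0.357 with scan day as a block (adjusted p = 0.0254) and 0.465 within scan day 2. The call ended with the mean of each gene's probe sets (adjusted p = 0.0964) and after quantile normalization (0.297, adjusted p = 0.052). Dhh (0.50), Cldn11 (0.73), Aqp8 (0.58) and Clu (0.62) had the largest moderated t, and 0 passed over all or adjusted over the list alone. Peritubular, vascular and matrix genes had a median of 0.412, 0.329 above all genes (adjusted p = 0.0119, and adjusted p = 0.605 with an estimated correlation). The median was 0.497 with scan day as a block (adjusted p = 0.0013) and 0.428 within scan day 2. Myh11 and Acta2, smooth muscle actin, passed adjusted over the list alone, Acta2 at 1.41 ± 0.417 (SE), and 0 members passed over all. Without Ku86 knockout replicate 2 the Sertoli median was 0.175 (adjusted p = 0.782) and the peritubular one was 0.314 (adjusted p = 0.204). Without wild type replicate 2 their adjusted p was 0.247 and 0.14. The 25 oxidative phosphorylation genes had a median of -0.109, or -0.193 relative to all genes (adjusted p = 0.0115, and adjusted p = 0.605 with an estimated correlation), which was -0.0959 with scan day as a block (adjusted p = 0.0536). After quantile normalization it was -0.0355 (adjusted p = 0.291), and without Ku86 knockout replicate 1 it was -0.184 (adjusted p = 0.0395). Cox6c, a cytochrome oxidase subunit, passed adjusted over the list alone at -0.65 ± 0.161 (SE). Tk1 (1.75 ± 0.388, SE) and Cdkn1c (-0.98 ± 0.242, SE) passed adjusted over lists that did not themselves pass.

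The arrays labelled double knockout were compared with wild type, by the labels for the effect of losing both, with Xrcc5 again against its label. Sertoli cell genes and peritubular, vascular and matrix genes rose with the smallest adjusted p of any list here, 5.98e-07 for both, and with an estimated correlation neither call held (adjusted p = 0.605 for both). Among Sertoli genes Cldn11, a tight junction protein, was 170 ± 30.8 against 48.8 ± 8.27 in wild type, and Ctsl, cathepsin L, 690 ± 125 against 192 ± 11.2 (SD, n = 2 each). Acta2 was 398 ± 144 against 86.1 ± 7.07, and Sparc, a matrix protein, 228 ± 53 against 71.3 ± 19.1. Itgb1, an integrin subunit, rose 3.95-fold from 151 ± 48.9 to 580 ± 41.6, and Pla2g12a fell to 378 ± 66.9. Limma called Itgb1 and Pla2g12a, 2 probe sets, with 626 (8.6%) of 7282 at an unadjusted p under 0.05. At an unadjusted p under 0.01 there were 142 higher and 26 lower probe sets. The log2 difference of Itgb1 was 1.98 ± 0.277 (SE, adjusted p = 0.0478), 1.57 within scan day 2 and 1.94 on its other probe set. That of Pla2g12a was -2.54 ± 0.338 (SE, adjusted p = 0.0478), -2.64 within scan day 2 and -0.99 on its other probe set. The calls of both genes ended after quantile normalization, with no filter, with no variance trend and with the experiment number as a block. Scan day as a block brought their adjusted p to 0.325 and 0.137, and both calls ended without wild type replicate 1, either double knockout array or Terc knockout replicate 1 (a count of 1, of another probe set, without double knockout replicate 2, and otherwise 0). Itgb1 also lost its call without Terc knockout replicate 2, Pla2g12a without wild type replicate 2, and the count was 4 without either Ku86 knockout array. Uncalled genes were Myh11 (at least 9.11-fold higher, with wild type at the floor), Cpt1a (2.94), Mpp3 (2.56), Xrcc5 (2.49, against its label) and Csrp1 (2.41). On the lower side they were Galnt6 (-1.72), Pex14 (-1.69), Cd37 (-1.45), Prl (-1.40) and Gpaa1 (-1.38). Other probe sets differed by 1.7 for Csrp1, -0.285 and -0.209 for Pex14, and -0.37 for Gpaa1.

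The Sertoli list had a median of 0.705 in the double knockout, 0.629 above all genes, with 15 of 17 members above 0 (adjusted p = 0.605 with an estimated correlation). It was 0.683 with scan day as a block (adjusted p = 4.9e-06) and 0.606 within scan day 2. Adjusted over the list alone 10 members passed, against 0 over all: Cst9 (1.35), Cldn11 (1.80), Ctsl (1.84), Clu (1.47), Wt1, Aard, Aqp8, Kitl, Gata4 and Dhh. The peritubular list had a median of 0.678, 0.602 above all genes, with 16 of 16 members above 0 (adjusted p = 0.605 with an estimated correlation). It was 0.900 with scan day as a block (adjusted p = 6.8e-07) and 0.848 within scan day 2. Adjusted over the list alone 7 members passed, against 0 over all: Myh11, Acta2 (2.16), Sparc (1.68), Dcn (1.09), Timp2, Timp3 and Tagln. Leydig cell genes had a median of 0.217 (adjusted p = 0.781) and macrophage and immune genes 0.0875 (adjusted p = 0.825). The 7 spermatogonia genes had a median of 0.743, 0.667 above all genes (adjusted p = 0.0217, and adjusted p = 0.605 with an estimated correlation), with Cd9 (1.98) and the germ cell RNA-binding protein Dazl (0.87) passing adjusted over the list alone. Their median was 0.514 with scan day as a block (adjusted p = 0.146) and 0.472 without double knockout replicate 1 (adjusted p = 0.145), and without wild type replicate 2 the adjusted p was 0.0567. Oxidative phosphorylation genes had a median of -0.157, or -0.233 relative to all genes (adjusted p = 0.0137, and adjusted p = 0.605 with an estimated correlation), and -0.121 with scan day as a block (adjusted p = 0.0695), with Cox6c at -0.72 ± 0.161 (SE). Quantile normalization gave them -0.0674 (adjusted p = 0.465), and leaving out double knockout replicate 1 gave -0.0631 (adjusted p = 0.0894) and replicate 2 -0.243 (adjusted p = 0.0165). Members of lists that did not pass were called adjusted over the list alone for Sesn1, a p53 target, at 1.24 ± 0.316 (SE), Igfbp6 (2.24), Igf2 (0.89) and Cdkn1c (-0.93).

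**Figure D2:**
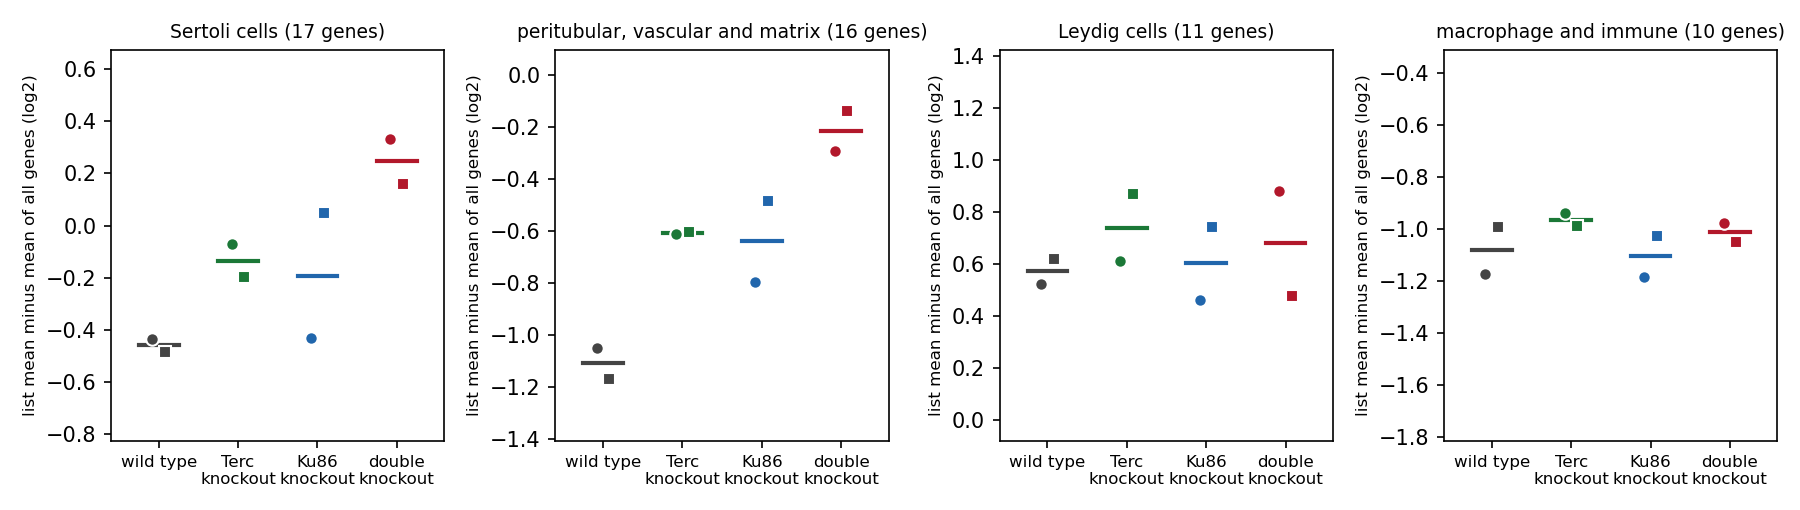
Mean log2 signal of 4 marker lists on each of the 8 arrays, less the mean of all genes on that array (y axis, log2, each panel spanning 1.5), by labelled genotype (x axis), with a circle for replicate 1, a square for replicate 2 and a bar at the group mean. The values that follow are medians over genes, not relative to all genes, and so are not the plotted means. The Sertoli list's median log2 difference from wild type in the double knockout was 0.705 and the peritubular list's was 0.678. It was 0.217 for Leydig cells and 0.0875 for macrophage and immune genes.

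The double knockout was compared with the Ku86 knockout, by the labels for the effect of losing Terc where Ku86 is lost. Pla2g12a read 378 ± 66.9 in the double knockout and 1760 ± 644 in the Ku86 knockout (SD, n = 2 each), a difference of -2.18 ± 0.338 (SE) that did not pass (adjusted p = 0.128). The difference was -1.61 within scan day 2 and -0.578 on its other probe set. Sertoli cell, peritubular and antioxidant genes rose as lists, each with an adjusted p of 0.605 with an estimated correlation. Limma called 0 of 7282 probe sets, with 245 (3.36%) at an unadjusted p under 0.05 and 0 with scan day as a block. The count was 2 without double knockout replicate 2 and 2 without Ku86 knockout replicate 1. The Sertoli median was 0.332 (adjusted p = 9.92e-05, and adjusted p = 0.605 with an estimated correlation), 0.560 within scan day 1 and 0.122 within scan day 2. The peritubular median was 0.391 (adjusted p = 0.00304, and adjusted p = 0.605 with an estimated correlation), 0.370 within day 1 and 0.480 within day 2. The 24 antioxidant genes had a median of 0.168 (adjusted p = 0.0137, and adjusted p = 0.605 with an estimated correlation), 0.243 within day 1 and 0.0822 within day 2. Scan day as a block gave adjusted p of 0.000363, 0.00276 and 0.0138 for the Sertoli, peritubular and antioxidant lists, but in scan day 2 alone the Sertoli and antioxidant calls ended (adjusted p = 0.411 and 0.295). Txn1, thioredoxin, passed adjusted over the antioxidant list alone at 1.43 ± 0.341 (SE), and 0 members of the other lists did. Uncalled genes were Tyro3 (2.88), Tpp1 (2.36) and Gfpt2 (2.24), with Tmem129 (-2.11) and prolactin, Prl (-1.98), on the lower side. Tyro3 read 10.7 and 67.5 on the Ku86 knockout arrays and differed by 1.24 within scan day 2. The other probe set of Tmem129 differed by -0.0653. Without double knockout replicate 2 the peritubular median was 0.215 (adjusted p = 0.0915), the Sertoli median 0.519 and the antioxidant adjusted p 0.0848, and without replicate 1 the peritubular median was 0.697. Without Ku86 knockout replicate 1 the Sertoli median was 0.192 (adjusted p = 0.0984), and the peritubular and antioxidant adjusted p was 0.106 and 0.342.

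The double knockout was compared with the Terc knockout, by the labels for the effect of losing Ku86 where Terc is lost. Xrcc5 was higher on the arrays labelled double knockout, 341 ± 116 against 41.2 ± 42.5 (SD, n = 2 each), against the direction of the label, and did not pass (3.51 ± 0.634, SE, adjusted p = 0.501). Hus1 stood at 50.8 ± 32.3 against 253 ± 54.5 and passed adjusted over the recombination list alone (-2.46 ± 0.552, SE) but not over all. Sertoli and peritubular genes rose as lists, with an adjusted p of 0.718 and 0.605 with an estimated correlation. Limma called 0 of 7282 probe sets, with 310 (4.26%) at an unadjusted p under 0.05 and 0 with scan day as a block. The count was 2 without double knockout replicate 2 or Terc knockout replicate 2, and 1 without Terc knockout replicate 1 or either Ku86 knockout array. The Sertoli median was 0.149 (adjusted p = 0.0139, and adjusted p = 0.718 with an estimated correlation), 0.239 with scan day as a block (adjusted p = 0.0148) and 0.0979 within scan day 2. Cst9 (1.06) and Cldn11 (1.45) passed adjusted over that list alone, and 0 over all. The peritubular median was 0.303 (adjusted p = 0.0285, and adjusted p = 0.605 with an estimated correlation), 0.582 with scan day as a block (adjusted p = 0.0029) and 0.519 within scan day 2, with 0 members passing either way. Kif11, a mitotic kinesin, passed adjusted over the proliferation list alone at 2.23 ± 0.525 (SE). Uncalled genes were Tyro3 (2.87) and the kinase Jak1 (2.59), with Fabp5 (-2.36) and Prl (-2.17) on the lower side. Fabp5 read 34.4 and 302.5 on the double knockout arrays, and differed by -0.796 within scan day 2 and -1.43 with scan day as a block. Without Terc knockout replicate 1 the Sertoli median was 0.072 (adjusted p = 0.0989) and the peritubular median 0.157 (adjusted p = 0.248), and without Terc knockout replicate 2 the Sertoli median was 0.350. Without double knockout replicate 1 they were 0.0979 (adjusted p = 0.0941) and 0.519, without double knockout replicate 2 the peritubular median was 0.0855 (adjusted p = 0.283), and without wild type replicate 2 its adjusted p was 0.0505.

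The interaction asked whether the effect of Terc loss differed between the Ku86 labels. Tmem129 had the largest value, -4.95 ± 0.711 (SE), and it did not pass (adjusted p = 0.124). It was higher in each single knockout (545 ± 167 and 395 ± 325) than in wild type (46.2 ± 14.2) or double knockout (123 ± 13.6, SD, n = 2 each). Its other probe set had an interaction of 0.2. Hus1 (-3.67 ± 0.781, SE) and Tk1 (-2.45 ± 0.549, SE) passed adjusted over the recombination and proliferation lists alone, and not over all. Limma called 0 of 7282 probe sets, with 367 (5.04%) at an unadjusted p under 0.05, and 0 of 23 lists passed, or 2 with scan day as a block. Uncalled genes were Derl1 (2.72), Polr2i (2.42) and Grn (2.17), with Mobp (-3.09) and Ddr2 (-2.83) on the lower side, and Xrcc5 had 0.62 ± 0.897 (SE). Other probe sets of Derl1 and Grn had 0.0749 and -0.274. The count was also 0 with scan day as a block, and 1 without Ku86 knockout replicate 1 or Terc knockout replicate 1. Across probe sets, which are not independent replicates, the Terc effect with Ku86 and the Terc effect without it had a correlation of -0.0315, with 47.2% of the same sign. For the Ku86 effect with and without Terc the correlation was -0.014, with 48.5% of the same sign, and it was 0.208 with scan day as a block, where the design alone gives 0.169 with no effect in any gene. Differences that share the wild type arrays correlated at 0.645 for the 2 single knockouts, 0.578 for the Terc and double knockouts, and 0.621 for the Ku86 and double knockouts. Simulated data with no effect and equal noise on every array gave 0.5, 0.501 and 0.5. Larger noise on the wild type arrays alone would raise all 3 correlations, so a shared effect of the knockouts was not shown.

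Averaged over Ku86 labels, Pla2g12a fell on the arrays without Terc by 2.29 ± 0.239 on the log2 scale (SE, adjusted p = 0.00477; 4 arrays against 4). This was the 1 probe set of 7282 that limma called (3 without double knockout replicate 2, 2 without Ku86 knockout replicate 2), with 385 (5.29%) at an unadjusted p under 0.05. It was -2.15 within scan day 2 and -2.44 with scan day as a block (adjusted p = 0.0512). Its other probe set averaged -0.99, and without wild type replicate 2 the value was -2.15 (adjusted p = 0.0766). The call also ended with no filter (adjusted p = 0.319) and with no variance trend (adjusted p = 0.217). Sertoli, peritubular and insulin-like growth factor lists rose, each with an adjusted p of 0.605 with an estimated correlation. The Sertoli median was 0.444 with 17 of 17 above 0 (adjusted p = 5.98e-07, and adjusted p = 0.605 with an estimated correlation), and 0.543 with scan day as a block (adjusted p = 4.47e-06) or 0.343 within scan day 2. The peritubular median was 0.488 (adjusted p = 1.32e-05, and adjusted p = 0.605 with an estimated correlation), and 0.455 with scan day as a block (adjusted p = 4.9e-06) or 0.395 within scan day 2. Timp2, Sparc, Dcn, Myh11, Acta2 and Timp1 passed adjusted over that list alone. The insulin-like growth factor median was 0.373 (adjusted p = 0.0304, and adjusted p = 0.605 with an estimated correlation), and 0.370 with scan day as a block (adjusted p = 0.00574). That call ended after quantile normalization (adjusted p = 0.0673) and without double knockout replicate 1 (0.0723), Terc knockout replicate 1 (0.076) or wild type replicate 2 (0.256). Gar1, a protein of the telomerase ribonucleoprotein, passed adjusted over the telomere list alone at 0.94 ± 0.279 (SE), and Hus1 over the recombination list at 2.32 ± 0.39 (SE). Uncalled genes were Blcap (1.75), Ppp1r15a (1.42) and Timp2 (1.28), with Icmt (-0.75) and Gng10 (-0.63) on the lower side.

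Averaged over Terc labels, Xrcc5 was higher on the arrays labelled Ku86 knockout by 3.20 ± 0.449 (SE), against the direction of the label, and did not pass (adjusted p = 0.0958). Sertoli and peritubular genes rose and oxidative phosphorylation genes fell as lists, each with an adjusted p of 0.605 with an estimated correlation. Limma called 0 of 7282 probe sets, with 375 (5.15%) at an unadjusted p under 0.05 and 0 with scan day as a block. The count was 1 without double knockout replicate 2, Ku86 knockout replicate 2 or either Terc knockout array. The Sertoli median was 0.291 (adjusted p = 0.00112, and adjusted p = 0.605 with an estimated correlation), and 0.263 with scan day as a block (adjusted p = 0.00237). Cldn11, Cst9, Ctsl and Clu passed adjusted over the list alone. The peritubular median was 0.331 (adjusted p = 0.000351, and adjusted p = 0.605 with an estimated correlation), and 0.501 with scan day as a block (adjusted p = 5.39e-05), with Myh11 and Acta2 passing adjusted over the list alone. Oxidative phosphorylation genes had -0.102 (adjusted p = 0.0230, and adjusted p = 0.605 with an estimated correlation), and -0.0807 with scan day as a block (adjusted p = 0.12). Their call also ended after quantile normalization (adjusted p = 0.226) and without double knockout replicate 1 (0.0723), either Ku86 knockout array (0.0504 and 0.0595) or Terc knockout replicate 1 (0.0809), and the median was -0.164 without double knockout replicate 2. Kif11 (1.69 ± 0.371, SE) and Gpx4 (-0.59 ± 0.146, SE) passed adjusted over lists that did not pass. Uncalled genes were Jak1 (2.11), with Agt (-0.92), Atp5md (-0.64) and Higd1a (-0.60) on the lower side. As list means tested by exact permutation of 4 arrays against 4, Sertoli genes differed by 0.325 between Ku86 labels (p = 0.143) and by 0.383 between Terc labels (p = 0.0857). Peritubular genes differed by 0.431 (p = 0.114) and 0.461 (p = 0.0857, exact permutation), where 0.0286 is the smallest p that 4 against 4 can give. Adjusted over the 23 lists these were 0.548 between Ku86 labels and 0.329 between Terc labels for both lists.

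Of 184 list tests 22 passed with the preset correlation, 18 of them higher and 4 lower, 34 passed with scan day as a block, and 0 passed with an estimated correlation, either without the block (lowest adjusted p = 0.605) or with it (lowest adjusted p = 0.907). The other 16 lists passed in no contrast without a block, and their medians in the double knockout against wild type follow. Of the repair groups, p53 targets had 0.198, non-homologous end joining -0.0174, homologous recombination 0.156 and telomere maintenance 0.0323. Germ cell lists had -0.0148 for spermatocytes, -0.0477 for round spermatids and -0.0868 for elongating spermatids. Erythroid genes had -0.495 and epididymis genes 0.113, where Clu, also a Sertoli gene, passed adjusted over the list alone. Apoptosis genes had 0.185, proliferation 0.0735, heat shock and unfolded protein 0.121, immediate early -0.0135 and interferon response -0.000766. For these lists and for the Leydig and immune lists the adjusted p in that comparison, with no block, was 0.134 or more. With the experiment number as a block, round spermatid genes passed in the Ku86 knockout against wild type (-0.137, adjusted p = 0.0496), and so did senescence genes in the double knockout (-0.198, adjusted p = 0.0496), where an estimated correlation was not run.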

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

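The fit to scan day 2 alone was chosen after the data had been seen, as were the list tests with scan day as a block and with median centring, and the cause of the shifts given here was not tested. Scan day 2 alone holds 5 arrays with 1 residual degree of freedom. A group left with 1 array was assumed to vary like the other groups. Between 15.6% and 26.0% of probe sets per array lay at or under the floor, which limits what can be measured for dim genes. Experiment numbers were not treated as pairs. The 6 correlations of deviations between groups ran from 0.0126 to 0.254, and 3 were over 0.1. With all 6 positive, each array must correlate best with an array of its own experiment number, as 8 of 8 did. Against wild type, limma put 514, 430 and 626 probe sets at an unadjusted p under 0.05 (Terc, Ku86 and double knockout). After quantile normalization these counts were 367, 344 and 484, so their size depended on scaling. With the experiment number as a block, and no quantile normalization, they were 734, 565 and 764, so a shared effect of the number stays possible. Every replicate 2 array was scanned on day 2, and of the replicate 1 arrays only that of the Terc knockout was. Such an effect can therefore hardly be told apart from scan day and chip lot.

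Counts of called probe sets against wild type were 2 for the Terc knockout, 3 for the Ku86 knockout and 2 for the double knockout, and in that order they were 0, 0 and 0 after quantile normalization, with no variance trend and with the experiment number as a block. They were 2, 0 and 1 after median centring and 0, 3 and 2 with the floor at the 5th percentile. With no floor but an offset of 11.8 added to every value, called no floor below, they were 2, 0 and 2. They were 0, 3 and 2 with the filter at the 60th percentile, 3, 4 and 8 with only the groups compared, and 1, 0 and 0 with scan day as a block. The 1 with scan day as a block was P4hb, named after its values were seen, which differed by 1.95 ± 0.204 (SE, adjusted p = 0.0423) with the block and 0.70 without it (adjusted p = 0.739). With no filter they were 9, 3 and 1, with 0 of the genes called otherwise among them, and scan day 2 alone gave 17, 15 and 30. For the double knockout against the Ku86 knockout the count of 0 became 4 with no filter and 13 in scan day 2. Against the Terc knockout 0 became 10 with no filter, 9 in scan day 2 and 1 with only the groups compared. The interaction count of 0 became 8 with no filter and 9 in scan day 2. Averaged Terc loss moved from 1 to 4 with no filter (without Pla2g12a), 0 with no variance trend, 0 with scan day as a block and 8 in scan day 2. Averaged Ku86 loss moved from 0 to 1 with the floor at the 40th percentile, with no floor, with the filter at the 60th percentile and at an adjusted p under 0.10, to 2 with no filter and to 20 in scan day 2. Leaving out each array gave 0 to 4, 0 to 3 and 0 to 4 against wild type, 0 to 2 for the double knockout against each single knockout, 0 to 1 for the interaction, 0 to 3 for averaged Terc loss and 0 to 1 for averaged Ku86 loss. The correlation between Ku86 effects, -0.014, was 0.208 with scan day as a block (where the shared day term alone gives 0.169), 0.109 in scan day 2 (0 from the design alone), and -0.0856 to 0.0876 without each array. That between Terc effects was -0.156 to 0.113 without each array.

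With an estimated correlation the medians of the Sertoli and peritubular lists against wild type stayed at 0.556 and 0.517 in the Terc knockout, 0.386 and 0.412 in the Ku86 knockout and 0.705 and 0.678 in the double knockout, with an adjusted p of 0.605 or more. The Sertoli list in the Ku86 knockout also missed the threshold with the mean of each gene's probe sets (0.386, adjusted p = 0.0964) and after quantile normalization (0.297, adjusted p = 0.052). Leaving out each array gave Sertoli medians of 0.433 to 0.556, 0.175 to 0.499 and 0.654 to 0.767 in the Terc, Ku86 and double knockouts, and peritubular medians of 0.322 to 0.734, 0.296 to 0.492 and 0.593 to 0.961. These 2 lists were singled out after all 184 list tests had been seen. For both in the double knockout against wild type, under 7 other settings and without each of the 8 arrays, only the estimated correlation ended the calls. Over settings and left-out arrays, the 6 results of these lists against wild type kept their side of the threshold 75 times and lost it 15 times, and the 16 other passing list results kept it 180 times and lost it 60 times. For named genes 1292 results kept their side, counting uncalled genes that stayed uncalled, 83 became weaker, 32 became stronger and 3 reversed. Every weaker result was of a called gene. Over settings and left-out arrays, calls held least often for Klk1b8, 5 times of 21. They held most often for Pla2g12a with averaged Terc loss, 16 times of 20. Those reversed were of uncalled Xrcc5: its interaction, 0.62, was -0.22 with the floor at the 40th percentile and -0.67 to 1.92 without each array, and its difference between Terc knockout and wild type, -1.03, was -2.33 to 0.27 without each array. The extremes came without Terc knockout replicate 1 or 2.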

Other observations

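The tests of scan day, of an odd wild type array, of fewer germ cells, of wrong labels and of DNA carried with Terc beside Pla2g12a were chosen after the results were seen, as were the list tests with scan day as a block. The test of fewer germ cells replaced earlier forms that permuted genes.

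Round spermatid and spermatocyte genes were lower than wild type in all 3 knockout groups with scan day as a block, and passed in none with no block. With the block and an estimated correlation 0 of the lists in this paragraph passed (adjusted p = 0.907 for each that passed with the block). Round spermatid genes had a median log2 difference from wild type of -0.155 in the Terc knockout (adjusted p = 0.0127), -0.340 in the Ku86 knockout (adjusted p = 3.67e-06) and -0.308 in the double knockout (adjusted p = 4.43e-05). Spermatocyte and meiosis genes had -0.270, -0.204 and -0.223 (adjusted p = 0.000994, 0.00461 and 0.00876). Elongating spermatid genes had -0.179 in the double knockout (adjusted p = 0.0158) and did not pass in the single knockouts (adjusted p = 0.0781 and 0.0536). Spermatogonia genes went the other way, passing in the double knockout without the block (0.743, adjusted p = 0.0217) and not with it (0.514, adjusted p = 0.146). Without the block the round spermatid medians were -0.138, -0.137 and -0.0477 (adjusted p = 0.102, 0.0756 and 0.171). The interaction with the block was 0.278 for spermatocyte genes (adjusted p = 0.0164) and 0.255 for round spermatid genes (adjusted p = 0.026), against 0.129 and 0.130 without it (adjusted p = 0.330 and 0.167). Round spermatid genes also passed with the block for averaged Ku86 loss (-0.215, adjusted p = 3.67e-06) and between the double and Terc knockouts (-0.138, adjusted p = 0.0404, against 0.0274 without it), and spermatocyte genes for averaged Terc loss (-0.130, adjusted p = 0.0164). Wild type replicate 1 is alone on its scan day, so with the block the wild type rests on replicate 2. Also with the block alone, and again with an adjusted p of 0.907 with an estimated correlation for each, p53 target genes passed for averaged Terc loss at 0.161 and proliferation genes at -0.109 (adjusted p = 0.0422 and 0.0427). Antioxidant genes passed there at 0.151 (adjusted p = 0.0422), proliferation genes at -0.157 between the double and Ku86 knockouts and insulin-like growth factor genes at 0.383 between the double knockout and wild type (adjusted p = 0.0443 for both).

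Xrcc5 signal was higher on every array labelled Ku86 knockout. A single wrong label would put 1 array out of place, whereas the lowest of the 4 arrays lay 1.78 above the highest of the others on the log2 scale, against a pooled SD of 0.984 between replicates. Scaling of dim signals also left it in place, as the averaged difference stayed between 2.78 and 3.22 over the scaling, floor and offset alternatives. Transcript merely kept at its usual level would not put the lowest array labelled Ku86 knockout, 259, over the highest with Ku86, 75.6. Ku86 labels exchanged on all arrays cannot be told apart from transcript raised by the targeted allele. The scanner's records name the genotype beyond the label for only 1 array and give no measurement. Either may hold, and the position of the probes in the transcript is not known here, so a probe outside the deleted part would check nothing.

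Sertoli and peritubular genes were higher in the double knockout than in wild type. Within scan day 2, with 1 array against 1, the medians were 0.606 and 0.848, and with scan day as a block 0.683 and 0.900, which scan day as the whole cause would not leave. They were at least 0.676 and 0.712 without either wild type array and 0.667 and 0.548 after quantile normalization. This argues against an odd wild type array and scaling. The Gapdh 3' to 5' signal ratio was 1.337 and 1.223 in the double knockout and 1.644 and 1.09 in wild type. The actin ratio was 1.388 and 2.034 against 1.619 and 1.615. The ranges overlapped, by 0.114 for Gapdh. Ranges of 2 arrays and 2 arrays can readily overlap, so RNA quality was not decided. Fewer germ cells were taken to raise all somatic types alike. Sertoli or peritubular signal less Leydig or immune signal separated the arrays of these groups in each of 4 pairs of lists. The separation was at least 0.399 on the log2 scale against a pooled SD of 0.228 between replicates. The lists were paired after their changes in this same comparison had been seen, which favours separation, so fewer germ cells were not decided. The round spermatid median was -0.308 with scan day as a block and -0.0477 without it. A change in Sertoli and peritubular cells with the genotype (other genotypes if the Ku86 labels were exchanged), differences between animals or in dissection, and somatic cells carried over if the samples were germ cell preparations, as the scanner's records have it, stay open and untested, and the calls did not hold with an estimated correlation (adjusted p = 0.605).

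Pla2g12a was lower on every array labelled Terc knockout. DNA of another strain carried beside Terc would act on nearby genes, and the 40 tested genes nearest Terc had a mean size of moderated t at percentile 87.8 of random lists, under the 95th percentile set for the test. Pla2g12a lies on the chromosome of Terc with 58 tested genes between them, so for this gene alone a carried segment and an effect of Terc loss cannot be told apart, and either may hold. For averaged Terc loss 3 of 35 splits of the 8 arrays into 4 and 4 gave as many called probe sets as the real 1, so chance was not excluded, and the highest other gave 12.

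The 40 tested genes nearest Xrcc5 stood at percentile 44 for averaged Ku86 loss. The count for that comparison was 0, which 35 of 35 splits must reach, so the splits tested nothing there. The highest split, with 12, set both double knockout arrays, Ku86 knockout replicate 2 and Terc knockout replicate 1 against the rest, which points to a structure of the samples whose cause was not tested. Of the 6 splits that set both double knockout arrays against both wild type arrays, 3 gave 0 called probe sets.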
